A study of environmental samples with 20 samples.

How the data were processed

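Genomic DNA from 20 soil samples of Axel Heiberg Island in the Canadian high Arctic was hybridised to 16S rRNA gene microarrays, with 1 array per sample. Per the labels' protocols, the DNA was eluted after RNA extraction from the same soil, bacterial 16S rRNA genes were amplified by touchdown PCR, and the product was labelled with the red dye cyanine 5. The samples came from an acidic soil, an upland tundra soil and a wet meadow soil. Each soil was sampled at the top 15 cm and at 40 cm, in 2008 (numbers 1 and 2) and in 2009 (number 3, and number 4 in the wet meadow). This gave 3 arrays for each depth of the acidic and upland soils and 4 for each depth of the wet meadow. The year alone was used, and no season was assigned, because the labels and the design text differ on the seasons.

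The deposited files are scanner output of 1 channel, with 528 spots per array in 4 blocks. Per the file headers, each spot's intensity is a mean of its pixels on a linear scale, the background is a median of the pixels around the spot, and laser power and photomultiplier gain were 80 on all 20 arrays. The headers name a lowess option, and the deposited tables give no normalised column, so the intensity values were treated as not normalised. The authors' deposited files also give a ratio of spot brightness to the SD of the background (the signal-to-noise ratio) and a percent of saturated pixels per spot, both written with decimal commas. The steps from DNA yield to loading of the arrays are not given in the sources used here.

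Spots lie in adjacent groups of 3. The median correlation of spots within a group was 0.619, against 0.355 for neighbouring groups, and each group of 3 was taken as 1 probe, which gives 176 probes. The columns for probe name and identifier are blank in all 20 files, and no probe list was used here. Probes are therefore named P001 to P176 by their print order, and no probe is tied to a taxon. For that reason the planned tests of taxon groups and of guilds were not run. The 16 probes at the corners of the blocks were bright on all arrays, were taken as orientation controls and were left out of the comparisons. Of the remaining 160 probes, 87 were above background on no array.

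From these files, the spot intensity was background-corrected by normexp with an offset of 50, put on the log2 scale, quantile-normalised between arrays without the corner spots, and averaged over the 3 spots of a probe. One spot (1 of 528 on 1 array) marked as bad was left out. A probe was called above background on an array where the median signal-to-noise ratio of its spots was at least 3, and the 65 probes above background on 2 or more arrays were tested. R 4.3.3, limma 3.58.1 and vegan 2.7.1 were used, with figures drawn by matplotlib 3.10.9.

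Soils and years were compared over 10 sites, where a site is a soil and sample number and its value is the mean of its log2 signal at both depths. The limma model held soil and year. Depths were compared over the 20 arrays in a limma model with 6 groups of soil and depth plus the year. Tests were two-sided, and a probe was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 differences come from these models and so are adjusted for year or soil, while means ± SD are of the normalised values as they stand. Where a probe was not above background on any array of a group, the difference is also given as at least N-fold, if that bound is above 1: the brighter group's mean against, per array, the higher of the lowest signal among probes above background and the probe's own signal. This bound allows for the background limit only, not for the spread between samples. Whole-profile comparisons used permutational analysis of variance (PERMANOVA) of Bray-Curtis distances between linear normalised signals, with 9999 permutations for soil and year, and all 1024 swaps within sites for depth. Numbers of probes above background were compared by exact permutation tests over sites and an exact sign-flip test over the 10 depth pairs. The depth differences in that number were compared between soils by exact permutation of the soil labels. On simulated data for the 65 probes with 12 changed, the comparison of acidic and wet meadow soil recovered 55.0% of changes of 1 log2 unit, 88.0% of 2 and 98.0% of 3, and the comparison of depths in the wet meadow recovered 44.0%, 83.5% and 96.0%. Of the calls, 5.86% and 4.28% were false. The simulated values had independent normal noise, with no background floor, saturation, scaling between arrays, or correlation within sites or plots. Recovery in the real data may therefore be lower.

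Before the data were examined, the named probes were set by rule. In a comparison with 5 or more calls they were the 20 calls with the largest difference, at most 12 per direction. In one with fewer calls they were every call and the 5 smallest p-values. Because no probe could be tied to a taxon, the text prints only the leading 2 per direction in most comparisons, and summarises the rest.

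Same-numbered samples of a soil's 2 depths deviated together: the correlation of their deviations from the group means over the 65 probes was above 0.1 in all 10 pairs (0.144 to 0.827). The numbers were therefore taken to pair the depths. After the year was also removed, 6 of the 10 pairs were above 0.1. The main depth model has no site block, as fixed before the data were examined, and the blocked counts are given where they differ.

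The labels call the samples separate samplings, and the p-values measure the spread between those samplings. Codes in the image names recur between years, so that the 10 sites appear to come from 6 plots, 2 per soil, of which 4 were sampled in both years; a soil's sites are then not all independent. The image names also place all 2008 arrays in one imaging session and all 2009 arrays in another. Year and imaging session therefore cannot be told apart, although each session holds all 3 soils and both depths. The arrays occupy 3 slide positions, and no acidic array lies at the third. The number of arrays limits the precision. The alternatives covered scaling, offset, filter, background correction, model, blocks, slide position, year, depth and each site left out.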

Results

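The series compared the bacterial community of 3 high Arctic soils, a question that its title ties to the soils' CO2 production. The array signal of 160 probes was measured in 20 soil samples: 3 acidic, 3 upland tundra and 4 wet meadow samples from each of 2 depths. Probes above background numbered 11 to 48 per array. The 3 soils together had 65 probes above background on at least 2 arrays, and 4 probes (P043, P052, P101 and P131) were above background on all 20. No probe is paired with a taxon in the files, so the results are given by probe. The arrays hold relative hybridisation signal and carry no CO2 measurement.

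Acidic soil gave the fewest probes above background. Averaged over both depths of each site, it had 21.7 ± 2.0 probes (SD, n = 3 sites), upland tundra 35.3 ± 4.4 (n = 3) and wet meadow 36.1 ± 9.3 (n = 4). By arrays, the means ranged from 18.7 ± 6.7 (SD, n = 3) in acidic soil at 40 cm to 38.7 ± 3.5 (n = 3) in the top of upland tundra. In an exact permutation test over the 4200 arrangements of the 10 sites the difference among soils did not pass 0.05 (p = 0.0681, two-sided, adjusted p = 0.2 over 6 comparisons). The permutations between soils did not hold the year, so that spread between years counts in them. The difference of 2009 minus 2008 was -7.17 probes (exact permutation p = 0.238, adjusted p = 0.357). Acidic minus upland tundra was -13.7 probes, with an exact permutation p = 0.1, the smallest p that 3 sites against 3 allow. Acidic minus wet meadow was -14.5 probes (exact permutation p = 0.0571, adjusted p = 0.2). Upland minus wet meadow was -0.792 probes (exact permutation p = 0.943), and its direction was not stable: it was -4.67 without wet meadow 3, 2.5 without wet meadow 1 and 1.71 with the signal-to-noise minimum doubled. The 2008 arrays averaged 22.2 ± 3.3 probes in acidic soil (SD, n = 4 arrays per soil), 37.8 ± 3.5 in upland tundra and 43.2 ± 4.1 in wet meadow. In 2009 acidic soil had 1 site, with 30 probes at the top and 11 at 40 cm, the array with the lowest corner intensity. The 2009 wet meadow arrays had 23 to 35 probes, so that the order of acidic soil and wet meadow in 2009 rests on that 1 array. With the signal-to-noise minimum doubled to 6, the difference among soils had an exact permutation p = 0.0124, which did not pass after adjustment over the same 6 comparisons either (adjusted p = 0.0743).

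**Figure D1:**
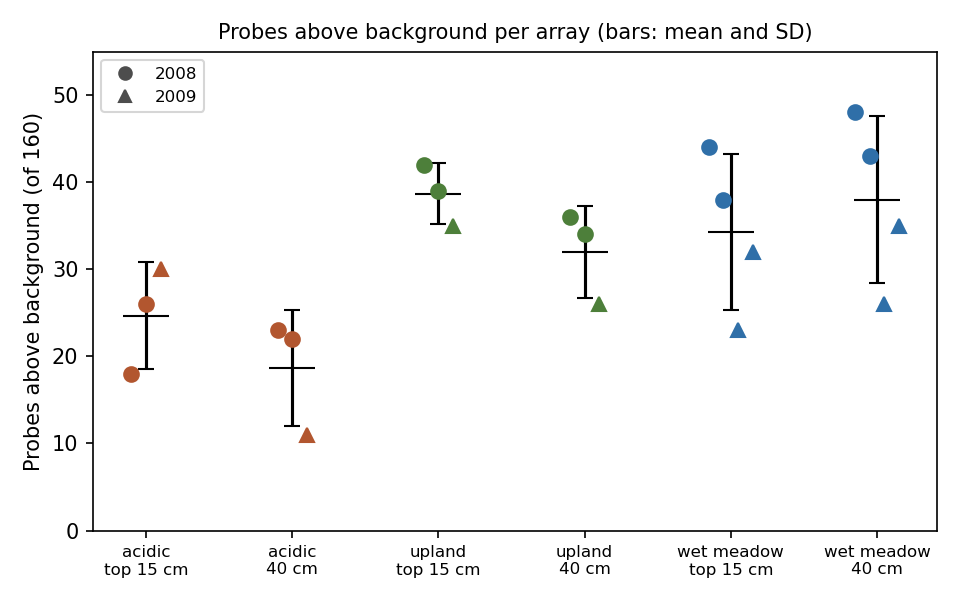
Number of probes above background (of 160, vertical axis) on each of the 20 arrays, by soil and depth, with circles for 2008, triangles for 2009, and horizontal and vertical bars for the group mean and SD. The 6 acidic arrays lie between 11 and 30, the 6 upland arrays between 26 and 42, and the 8 wet meadow arrays between 23 and 48.

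With the sites taken as separate samplings, the whole probe profile differed between soils, between years and between depths. Soil accounted for 38.4% of the variation in Bray-Curtis distance among the 10 sites after year (permutation test of distances, p = 0.0004), and year for 32.3% after soil (permutation p = 0.0002). These permutations ran freely over the 10 sites, with no plot block. They were not confined within soils for the year or within years for soil, so their p-values are not those at a fixed soil or year. The sites appear to come from 2 plots per soil, too few for a permutation p under 0.05 between soils at the level of plots. Depth accounted for 4.73% of the variation among the 20 arrays (p = 0.0234 by all permutations within sites), a total that also holds the differences between sites, so that this share is not comparable with the other 2. On the top 15 cm arrays alone, soil accounted for 28.1% and did not pass (permutation p = 0.0546), while on the 40 cm arrays alone it accounted for 34.6% (permutation p = 0.0081). The depth result was lost in 4 of the 10 runs that left out 1 site (permutation p = 0.0586 without acidic 1, 0.0508 without upland 3, 0.0586 without wet meadow 1 and 0.0664 without wet meadow 4).

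**Figure D2:**
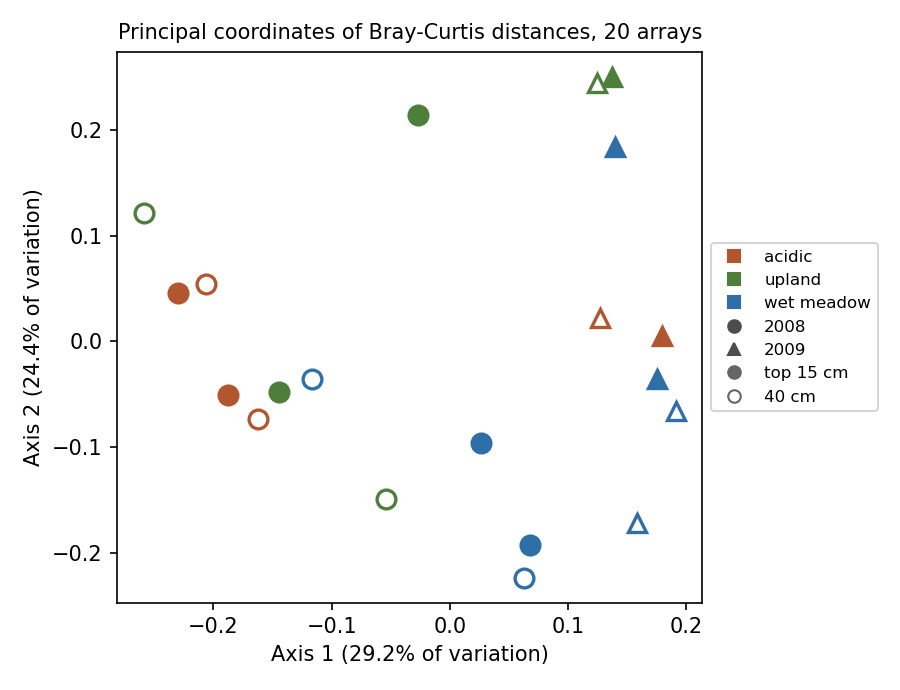
Principal coordinates of Bray-Curtis distances between the 20 arrays, with axis 1 (29.2% of the variation) horizontal and axis 2 (24.4%) vertical; colour marks soil, shape marks year, and filled or open symbols mark the top 15 cm or 40 cm. All 2009 arrays lie at 0.124 or higher on axis 1 and all 2008 arrays at 0.0679 or lower.

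Among all 3 soils, 5 of 65 probes differed (limma F test, adjusted p under the threshold; 24 at an unadjusted p under 0.05): P030, P050, P038, P014 and P015. P030 and P014 were above background in no acidic or upland array, and in 7 and 5 of the 8 wet meadow arrays. The log2 signal of P030 was 10.41 ± 0.40 in wet meadow (SD, n = 4 sites), 8.55 ± 0.18 in acidic soil (n = 3) and 8.26 ± 0.22 in upland tundra (n = 3). P050 was also brightest in wet meadow (12.86 ± 0.47), followed by upland tundra (11.28 ± 0.99) and acidic soil (9.77 ± 0.48). P038 had the opposite order, with 12.80 ± 0.37 in acidic soil, 11.58 ± 0.40 in upland tundra and 10.73 ± 0.61 in wet meadow. On the 2008 sites alone, 2 per soil, 1 probe passed and it was none of these 5; with slide position as a covariate none did, and with all 20 arrays and the site as a random block 14 did. Leaving out acidic 1, acidic 3 or upland 1 gave 3, 9 or 15 calls.

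Acidic soil and wet meadow, the pair with the most calls, differed at 14 of 65 probes, 8 higher and 6 lower in acidic soil (limma). Wet meadow was brighter at P050, where acidic soil was lower by a log2 difference of -3.17 ± 0.45 (SE, adjusted p = 0.00274), and at P030, with a difference of -1.88 ± 0.25 (adjusted p = 0.00274). P030 was not above background in any acidic array, which bounds the difference at at least 1.41-fold. Both calls held in all 10 runs that left out 1 site. The call for P050 was lost under 3 of 17 alternatives (-4.07 to -2.28) and that for P030 under 1 of 16 (-2.35 to -1.56). Acidic soil was brighter at P038, with a difference of 1.99 ± 0.32 (adjusted p = 0.00420) and at P094, with 2.24 ± 0.66 (adjusted p = 0.0435). The call for P038 held in all 10 runs that left out 1 site and was lost under 5 of 17 alternatives. Its difference fell to 0.46 with median centring (adjusted p = 0.179) and 0.91 with the share of total signal (adjusted p = 0.108), and was 0.29 before any scaling (adjusted p = 0.443). The call for P094 was lost in 7 of the 10 runs that left out 1 site (1.72 to 3.09) and under 12 of 17 alternatives (1.12 to 3.65). P094 was above background in 4 of 6 acidic and 3 of 8 wet meadow arrays, all of them from 2008. The split of higher and lower calls depended on the scaling: with arrays centred on their median it was 0 higher and 11 lower, and with signal as a share of the array total 1 higher and 3 lower. Median centring shifted the median difference of the 65 probes to -0.53, from -0.04 under quantile scaling, and the difference for 4 of the 8 higher calls then turned negative. This centring used all spots outside the corners. At most 48 of the 160 probes were above background on an array, so it mainly aligns background spots and can leave dimmer arrays dim. Fewer probes passed with the replicate number as a block (7), with slide position as a covariate (2) and on the 2008 sites alone (1). The count was 4, 6 or 8 without acidic 1, 2 or 3, 8 or 5 without upland 2 or 3, and 6, 6, 8 or 7 without wet meadow 1, 2, 3 or 4.

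Acidic soil and upland tundra gave no call after adjustment (limma, 0 of 65; 16 at an unadjusted p under 0.05). The largest difference was at P114, which was above background in all 6 upland arrays, in 5 of 8 wet meadow arrays and in no acidic array. Its log2 signal was 13.24 ± 2.32 in upland tundra (SD, n = 3 sites) and 8.27 ± 0.24 in acidic soil (n = 3), a difference of -4.97 ± 1.21 (SE, limma's adjusted p = 0.0797). By the means, upland tundra was at least 10.03-fold brighter, a figure that leaves out the spread of its 3 sites. Median centring gave 0 higher and 6 lower calls in acidic soil, and the share of total signal 1 higher and 3 lower. The top 15 cm arrays alone gave 5 calls, and leaving out upland 1 gave 3.

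Upland tundra and wet meadow differed at 2 of 65 probes, both lower in upland tundra (limma; 12 at an unadjusted p under 0.05). P030 had a log2 difference of -2.17 ± 0.25 (SE, adjusted p = 0.00131), which bounds wet meadow at at least 2.95-fold brighter. P014 had a difference of -1.47 ± 0.25 (adjusted p = 0.0114), at least 1.38-fold. The call for P030 held under all 16 alternatives and in all 10 runs that left out 1 site, and neither probe was among those tested under the stricter filter that gave 0 calls. P050, at -1.66 ± 0.45, did not pass (adjusted p = 0.102). With slide position as a covariate P014 no longer passed (adjusted p = 0.0739; range over its alternatives 0.000279 to 0.411), and leaving out upland 1, 2 or 3 gave 7, 1 or 1 calls.

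**Figure D3:**
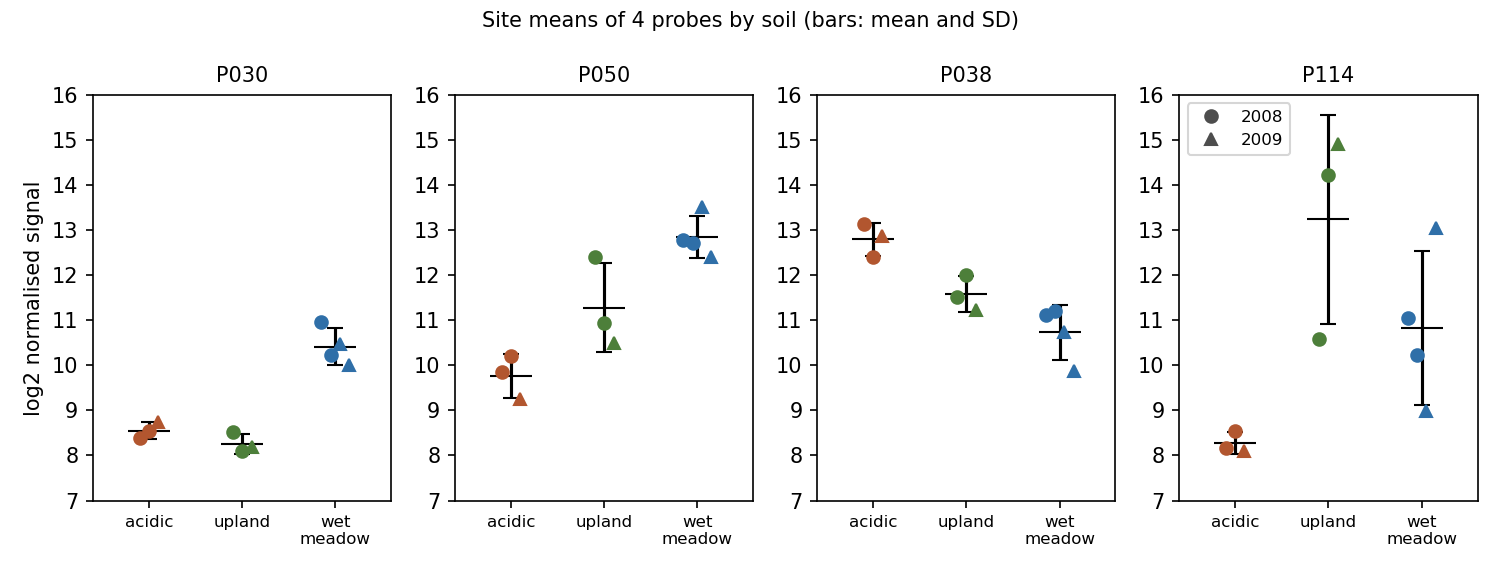
Log2 normalised signal (vertical axis) of P030, P050, P038 and P114 in each of the 10 sites by soil, each point a mean of both depths, with circles for 2008, triangles for 2009, and bars for the soil mean and SD. All 4 wet meadow sites lie above all 6 other sites at P030, and P114 averages 8.27 in acidic soil and 13.24 in upland tundra.

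Depth moved few probes. Over the 3 soils, 2 of 65 probes differed between 40 cm and the top 15 cm (limma; 10 at an unadjusted p under 0.05). P015 was higher at 40 cm by 1.06 ± 0.25 log2 units (SE, adjusted p = 0.0423) and P026 was lower there, with a difference of -0.45 ± 0.12 (adjusted p = 0.0423). P015 was above background in 5 of 10 arrays at 40 cm and 1 of 10 at the top. P026 was so in 0 of 10 and 5 of 10, and as its mean at the top does not exceed the background limit, no fold change above 1 can be bounded and the size of its difference is not measured. With the site as a random block 4 probes passed. With the site as a fixed block 2 passed, P015 (adjusted p = 0.00645) and P027 (-1.43, adjusted p = 0.0197), while P026 did not (adjusted p = 0.134). Within the 2008 or the 2009 arrays alone, or with slide position as a covariate, 0 passed. Leaving out acidic 3, upland 2, upland 3 or wet meadow 4 gave 0 calls, upland 1 or wet meadow 2 gave 1, and wet meadow 3 gave 6; P015 was lost in 4 and P026 in 7 of these 10 runs. Over all soils, the number of probes above background gave no depth difference past 0.05: 40 cm minus top was -2.3 probes (SD of the 10 differences 7.82, lower in 5 of 10 sites, exact sign-flip p = 0.424, and -0.444 without acidic 3). By soil it fell in all 3 upland pairs (-6.67 ± 2.08, SD) and rose in all 4 wet meadow pairs (3.75 ± 0.96), an exact permutation p = 0.0286 for that pair of soils (adjusted p = 0.114 over 4 comparisons, which were chosen after the data were seen). In acidic soil it was -6 ± 12.1, lower in 2 of 3 pairs.

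The wet meadow held 3 depth calls among 65 probes (limma; 10 at an unadjusted p under 0.05). P015 was above background in all 4 arrays at 40 cm and in none of the 4 at the top. Its log2 signal was 10.96 ± 0.81 at 40 cm and 8.71 ± 0.28 at the top (SD, n = 4 each), a difference of 2.25 ± 0.39 (SE, adjusted p = 0.00214), at least 3.36-fold. P026 was lower at 40 cm (-0.78 ± 0.18, adjusted p = 0.0177), at least 1.02-fold, and so was P031 (-2.18 ± 0.59, adjusted p = 0.0442). P031 was above background in all 4 top arrays and in 1 of 4 at 40 cm. P026 was so in 2 of 4 top arrays and in 0 of 4 at 40 cm, so that its difference lies near the background limit. With the site as a fixed block 2 calls remained, P015 (adjusted p = 0.000449) and P031 (adjusted p = 0.0361), and P026 no longer passed (adjusted p = 0.0731). Within the 2008 arrays alone P015 differed by 2.35 (adjusted p = 0.130), and within the 2009 arrays alone by 2.14 (adjusted p = 0.328), so that no call was made within a single year. P031 differed by -3.02 in 2008 and -1.34 in 2009, and P026 by -0.59 and -0.98. Of the 10 runs that left out 1 site, P015 kept its call in all, while P031 was lost in 6 and P026 in 4. With slide position as a covariate P015 was the only call (adjusted p = 0.0171; range over its alternatives 0.000449 to 0.328), and the count was 1 without upland 3, wet meadow 2 or wet meadow 4 and 5 without wet meadow 3.

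**Figure D4:**
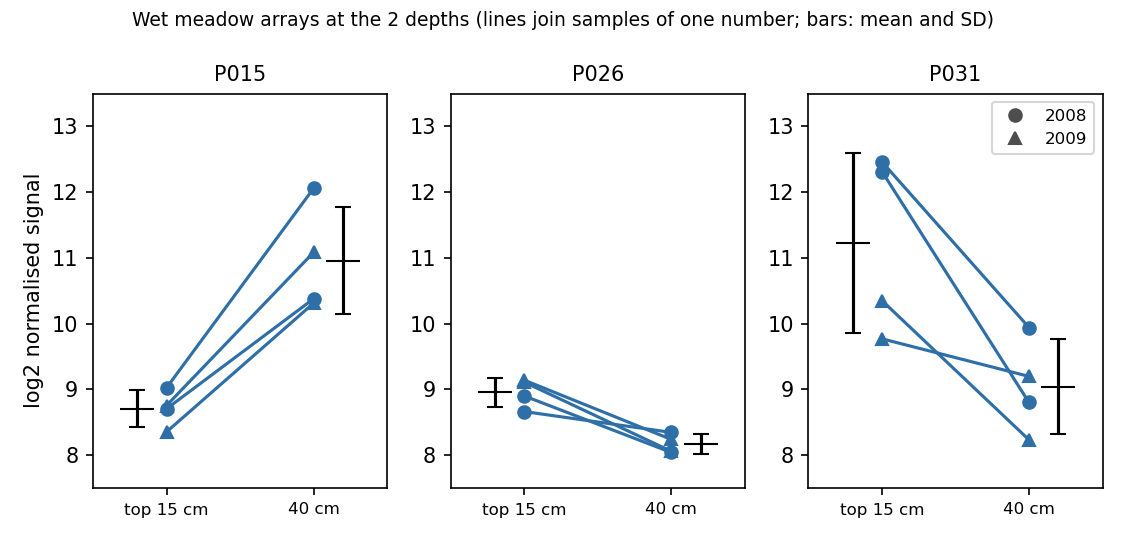
Log2 normalised signal (vertical axis) of P015, P026 and P031 in the 8 wet meadow arrays at both depths, with lines joining samples of one number, circles for 2008, triangles for 2009, and bars for the mean and SD. P015 rises with depth in all 4 pairs, from a mean of 8.71 to 10.96.

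Depth gave no call in acidic soil (limma, 0 of 65; 4 at an unadjusted p under 0.05) or in upland tundra (limma, 0 of 65; 2 at an unadjusted p under 0.05). The smallest p in acidic soil belonged to P108, at 1.29 ± 0.32 log2 units higher at 40 cm (SE, adjusted p = 0.0605), and the site as a random block gave 1 call there. In upland tundra it belonged to P026, with a difference of -0.77 ± 0.21 (adjusted p = 0.116), at least 1.25-fold, and median centring gave 2 calls there, both lower at 40 cm. The change with depth was not shown to differ between soils: 0 of 65 probes passed the interaction test (limma; 4 at an unadjusted p under 0.05). Its smallest p belonged to P033 (adjusted p = 0.122), which was above background in all 3 top arrays of upland tundra and in no other array.

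Sampling year separated 12 of 65 probes, 10 higher and 2 lower in 2009 (limma; 20 at an unadjusted p under 0.05). The probe with the largest difference was P094, above background in 11 of 12 arrays of 2008 and in none of the 8 of 2009. Its log2 signal was 13.23 ± 1.74 in 2008 (SD, n = 6 sites) and 8.08 ± 0.18 in 2009 (n = 4), a difference of -4.83 ± 0.56 (SE, adjusted p = 0.000399), at least 13.7-fold. P158 was also lower in 2009 (-0.97 ± 0.27, adjusted p = 0.0365), a call lost in 4 of the 10 runs that left out 1 site and under 4 of 15 alternatives (-0.34 with the share of total signal). P135 was higher in 2009 by 2.12 ± 0.18 log2 units (adjusted p = 5.15e-05) and P052 by 1.98 ± 0.15 (adjusted p = 3.49e-05). The split of higher and lower calls was 5 and 4 with median centring and 23 and 2 with the share of total signal, which moved the median difference to 0.48. The 40 cm arrays alone gave 4 calls. All 2009 arrays were imaged in a session of their own, so that the year and the session cannot be told apart. The corner probes averaged an intensity of 57591 ± 2855 in 2008 (SD, n = 6 sites) and 47443 ± 4503 in 2009 (n = 4). The saturated spots outside the corners numbered 6.58 ± 2.69 in 2008 and 0.375 ± 0.479 in 2009. Before scaling, the total signal of those spots above background ran from 3.14e+05 to 7.47e+05 per array in 2008 and from 1.11e+05 to 4.41e+05 in 2009. The calls are therefore relative to the other probes of an array.

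**Figure D5:**
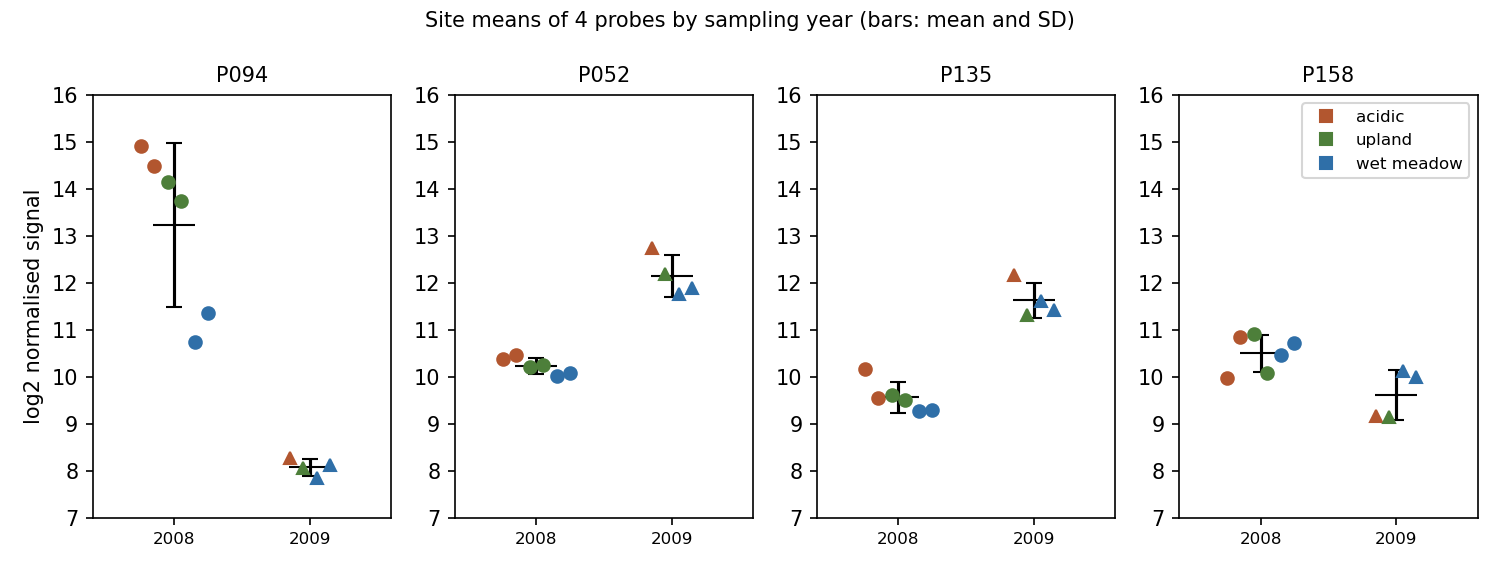
Log2 normalised signal (vertical axis) of P094, P052, P135 and P158 in each of the 10 sites by sampling year, each point a mean of both depths, coloured by soil, with bars for the year's mean and SD. At P094 the 2009 sites average 8.08, and at P052 and P135 every 2009 site lies above every 2008 site.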

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

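The tests of slide position, whole-array signal, scaling direction, imaging session and depth change in probe number were chosen after the results were seen. No sample of the wet meadow groups stood far from the other 3 in the number of probes above background, corner intensity or any called probe (0 of 54 tests passed Dixon's critical value). The depth difference in probes above background went opposite ways in 2 soils. It was negative in all 3 upland pairs (-9 to -5) and positive in all 4 wet meadow pairs (3 to 5), and upland minus wet meadow was -10.4 probes (exact permutation p = 0.0286, the smallest that 35 arrangements allow, and adjusted p = 0.114 over 4 comparisons). The 2 depths lay at different slide positions in all 3 upland and 2 of the 4 wet meadow pairs. Signal appeared in data that the comparisons do not use. The corner probes averaged an intensity of 53532 over the 20 arrays, with array means from 29440 to 61272, and the lowest was the acidic sample 3 at 40 cm, which also had the fewest probes above background (11). Another 8 probes were above background on exactly 1 array, 5 of them in the wet meadow, 2 in upland tundra and 1 in acidic soil.

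Acidic soil had the fewest probes above background. Before any scaling, 58 of the 65 tested probes had a lower signal in acidic soil than in the mean of the other soils, 18 of them past the threshold, with 0 past it in the other direction. If a weaker signal over whole arrays were the cause, no probe would fall below the shift of the unsaturated probes that were above background everywhere (3 probes, mean -0.999). Of the 62 others, 18 lay below it, 1 of them past the threshold (P050, -2.34 ± 0.38, adjusted p = 0.0109). A single common shift alone does not give this if the 3 probes are the same in all soils. They were chosen from these data, however. After quantile scaling P052 and P131 among them were called higher in acidic soil than in wet meadow, a direction that median centring reversed. Were that rise real, such a reference would make other probes look lower in acidic soil. Before scaling, however, the 3 fell further there than the median of the 65 probes (-0.624). Of the 62, 2 lay above the shift of the 3 past the threshold, P128 (1.59 ± 0.33, adjusted p = 0.0331) and P101 (0.92 ± 0.21, adjusted p = 0.0438). P128 was above background in 3 acidic arrays and 1 wet meadow array (0.59 ± 0.27 before scaling, adjusted p = 0.116), and P101 has saturated pixels on at least 1 array. Saturation can shrink a fall in signal at P101. A floor can shrink a fall but not turn it into a rise, and the rise of P128 before scaling did not pass. These 2 therefore do not settle it. A common factor stays open for the other probes. At the first slide position alone the acidic arrays had 18.3 ± 7.5 probes (SD, n = 3) and the others 38 ± 8.2 (n = 5), exact permutation p = 0.0536. At the second position the acidic arrays had 23, 22 and 30 probes, the upland array 35 and the wet meadow array 44. Acidic soil was thus lower on average at both shared positions, but as the test did not pass, slide position is not excluded. A less diverse acidic community may also give fewer probes, which the design names but which these arrays cannot set apart from lower DNA yield or labelling.

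The direction of the calls between acidic soil and wet meadow rests partly on the scaling. Of the 8 probes called higher in acidic soil, 4 were also higher before any scaling. Of these, P094 passed before scaling (limma adjusted p = 0.0419), and P038, P148 and P128 did not (0.443, 0.184 and 0.240). All 6 called lower were also lower, which carries little weight. Before scaling, 58 of the 65 tested probes were lower in acidic soil than in the mean of the other soils. Quantile scaling, which gives all arrays one distribution, may have lifted the dimmer acidic arrays at the higher calls that lost their direction. The 4 that kept their direction do not settle it, and a relative gain of those bacteria in acidic soil stays open. In other splits of the 7 sites, the highest number of calls was 1 against the observed 14 (1 of 35 splits as large, the real one). This share is the smallest that 35 splits allow and was not adjusted over the comparisons. It also needs the sites to be separate samplings, so chance is not excluded. The sites appear to come from 2 plots per soil, too few for a share under 0.05 between plots, and the plot code as a random block left 7 calls.

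Year and imaging session coincide. The headers give a laser power and photomultiplier gain of 80 on all 20 arrays, so no change of these settings is recorded. A single change of gain not recorded there would move all probes one way. Before scaling, 4 probes were lower and 5 higher in 2009 past the threshold, which argues against gain alone. A change of slide lot, labelling or hybridisation between sessions stays open, since 0 samples of one year were imaged in both sessions. A real change between years is equally open and untested. Of 100 splits of the 10 sites, 1 gave as many as the observed 12 calls (the real one, highest other 5). This share is the smallest that 100 splits allow and was not adjusted over the comparisons. It also needs the sites to be separate samplings, so chance is not excluded. With the plot code as a random block 13 probes were called.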

How the results depend on the processing

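Alternatives of slide position, background correction, median pixels, plot blocks, single-year depth fits and the depth difference in probe number were chosen after seeing the data. Counts of calls in the main fits were 5 for the soils together, 0 acidic against upland, 14 acidic against wet meadow, 2 upland against wet meadow, 2 for depth, 0, 0 and 3 for depth in acidic, upland and wet meadow soil, 0 for the interaction and 12 for year. The cause was not tested where a count moved, except where fewer probes or samples were used.

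Median centring gave 10 for the soils together, 6 acidic against upland, 2 for depth in upland and 2 for the interaction. It reversed P131 (-0.66), P017 (-0.040), P140 (-0.31) and P052 (-0.55) between acidic soil and wet meadow, and P131 (-0.011) between years. The share of total signal gave 4 acidic against upland, 4 acidic against wet meadow, 6 for depth in the wet meadow and 25 for year, and reversed P131 (-0.21) and P052 (-0.10) between acidic soil and wet meadow. The smaller offset gave 1 and the offset at a percentile 4 for depth. The stricter filter, with 28 probes tested, gave 2 for the soils together, 3 acidic against wet meadow, 0 upland against wet meadow, 0 for depth, 1 for depth in acidic soil and 0 in the wet meadow. Acidic against wet meadow fell to 7 with a trended, robust prior, 6 without the year term, 6 with median pixels and 7 with the plot code as a random block; depth fell to 0 without the year term.

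With the site as a random replicate block, depth gave 4 calls and depth in acidic soil 1; with a fixed block no count moved by over 1.5 times, but P026 was lost over all soils and in the wet meadow, which then had 2 calls. The replicate number as a block across soils gave 7 acidic against wet meadow, and changed no other call count by over 1.5 times. All 20 arrays with a random site block gave 14 for the soils together and 3 acidic against upland. The top arrays alone gave 5 acidic against upland and 8 acidic against wet meadow, and a community share for soil of 28.1%, no longer past the threshold. The 40 cm arrays alone gave 4 acidic against wet meadow and 4 for year. The 2008 sites alone gave 1 for the soils together and 1 acidic against wet meadow. Slide position as a covariate gave 0 for the soils together, 2 acidic against wet meadow, 1 upland against wet meadow, 0 for depth and 1 for depth in the wet meadow. No background correction gave 0 for depth and 1 for depth in the wet meadow, and median pixels 1 acidic against upland. The 2008 arrays alone gave 0 for depth and 0 for depth in the wet meadow, as did the 2009 arrays alone (0 and 0).

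With the signal-to-noise minimum doubled, the permutation p among soils became 0.0124, acidic minus wet meadow -11.0 probes (p = 0.0286), neither past 0.05 after adjustment over the 6 comparisons (0.0743 and 0.0857), and upland minus wet meadow turned to 1.71. The calls kept under all alternatives run were P030 between upland and wet meadow (not tested under the stricter filter) and P043, P052, P094 and P135 between years.

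Leaving out each site in turn gave 3 to 15 calls for the soils together, 0 to 3 acidic against upland, 4 to 13 acidic against wet meadow, 1 to 7 upland against wet meadow, 0 to 6 for depth, 0 to 1 for depth in acidic soil, 0 to 0 in upland, 1 to 5 in the wet meadow, 0 to 0 for the interaction and 8 to 13 for year. Without upland 1 the soils together gave 15; without acidic 3 depth gave 0, and without wet meadow 3 it gave 6. Community shares ran from 34.4% to 47.3% for soil, 24.5% to 36.7% for year and 4.18% to 5.73% for depth, whose p rose past the threshold in 4 of the 10 runs. For probes above background, the p among soils ran from 0.0143 (without wet meadow 3) to 0.154, acidic minus upland from -16.1 to -11.8, acidic minus wet meadow from -18.3 to -11.2, upland minus wet meadow from -4.67 to 2.5, and depth from -3.11 to -0.444. The depth difference in upland minus that in wet meadow was -10.4 probes, -11.4 with the doubled minimum, and -11.2 to -9.25 when each site was left out, with p past 0.05 in 7 of the 10 runs, where 15 or 20 arrangements allow no smaller p. The alternatives for taxon groups and guilds were not run, since no probe names were at hand. Signal over background limits the tests to 65 of 160 probes.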

Other observations

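The comparison of plots was chosen after the distances were seen; the splits of the samples were planned. Probes of a single soil, above background on at least 2 of its arrays and on none of the other soils', numbered 7 in the wet meadow, 3 in upland tundra and 0 in acidic soil, against 55, 44 and 28 probes above background on at least 2 arrays of each. These counts can rise with the number of arrays, of which the wet meadow has 8 and the others 6 each. Among the wet meadow's were P030 (7 of 8 arrays), P013 and P014 (5 of 8 each) and P051 (4 of 8). P013 and P014 are neighbours on the array and adjoin P015, the probe with the largest depth difference there, which was above background in 2 upland arrays as well. The 3 upland probes (P033, P099 and P115) were above background only in top arrays, in 3, 2 and 2 of them. These probes were singled out after their values were seen.

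The 2 depths of one site had a mean Bray-Curtis distance of 0.189 ± 0.024 in acidic soil (SD, n = 3 sites), 0.220 ± 0.122 in upland tundra (n = 3) and 0.333 ± 0.117 in wet meadow (n = 4), differences that were not tested. The soils overlap: the closest pair of all was upland 3 (0.0793), and wet meadow 1 (0.175) lay within the acidic range of 0.163 to 0.212. Over all soils, arrays of one number at different depths were 0.256 ± 0.112 apart (10 pairs), arrays of one soil and year with different numbers 0.318 ± 0.086 (16 pairs), and arrays of other soils in the same year 0.360 ± 0.089 (68 pairs). Arrays of one soil from different years that share no plot code and depth were farther apart than these, at 0.396 ± 0.072 (24 pairs). Arrays of other soils and other years were 0.451 ± 0.055 apart (64 pairs).

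A hypothesis was that a plot keeps its own profile between years. Arrays of one plot code and depth from different years were 0.353 apart on average, against 0.414 when the 2 plots of every soil were exchanged. Of the 8 possible pairings, 2 had a mean distance as low, the observed one included, and 8 pairings cannot give a share under 0.05, so the hypothesis stays open.

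Other splits of the samples were counted for each model, and the shares were not adjusted over the models. For the 3 soils together, 1 of 100 splits gave as many as the observed 5 calls, the real one (highest other 2). With no adjustment over the models, and with the sites taken as separate samplings, chance is not excluded. Between 2 plots per soil no share could fall under 0.05, and the plot code as a random block left 4 calls. For upland tundra and wet meadow, 3 of 35 splits gave as many as the observed 2 calls (highest other 4), so chance is not excluded by this count. For depth over all soils, 2 of 100 splits within sites gave as many as the observed 2 calls (highest other 2). With no adjustment over the models, and with P026 lost when the site was a fixed block (limma adjusted p = 0.134), chance is not excluded. For depth in the wet meadow, 2 of 35 splits gave as many as the observed 3 calls (highest other 3), and chance is not excluded. The other split parted fewer pairs, and among the 8 splits that part all 4 pairs the real one alone reached 3 (highest other 1). As 8 splits cannot give a share under 0.05, this count does not exclude chance either. Acidic soil against upland tundra, depth in acidic soil and depth in upland tundra have only 10 splits each, too few for a share under 0.05. Each had an observed 0 calls, which all 10 splits reach, with highest others of 0, 4 and 0. The 4 calls in acidic soil came from a split that parts 1 pair. For the interaction of depth and soil the observed count was 0, which all 100 splits reach (highest other 1).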
